A study of Rattus norvegicus with 24 samples.

How the data were processed

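Gene expression was measured in 24 samples of rat lung that fell into 8 groups of 3: a control and 5, 10 and 20 mg/mL of whole-cigarette smoke condensate (WCSC), each at 6 and at 12 days. Per the labels' protocols, RNA was extracted with Trizol and total RNA went into libraries made with a Lexogen QuantSeq kit, which sequences the ends of polyadenylated transcripts. The submitters' processing notes name Bowtie2, bedtools and the rat genome build rn6. Their versions, the gene annotation, the read filters and the strand setting of the counting are not given in the sources used here. The files that the authors deposited hold raw read counts per gene symbol, 1 file per sample, and the values were checked to be whole numbers whose totals differ between samples. The labels do not say whether the replicates of a group were separate animals, so the p-values of single genes below measure the spread between samples.

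Each file had 17048 lines and 16881 distinct symbols. The 167 lines whose symbol was repeated held 0.772% of the counts and were left out. Total counts per sample ranged from 4.80e+06 to 1.11e+07 with a median of 6.84e+06. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 11421 genes for testing. Counts were scaled by TMM (factors from 0.804 to 1.12) and fitted with the edgeR quasi-likelihood method in 1 model of the 8 group means over all 24 samples, with 16 residual degrees of freedom. The common biological coefficient of variation was 0.335. Contrasts compared each dose with the control of its day, a slope linear in dose (0, 5, 10 and 20 mg/mL) within each day, the 20 mg/mL effect at day 12 minus that at day 6, and the controls of the 2 days. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Intervals are 95% intervals from the same fit. CPM are the counts-per-library-size values of the edgeR cpm function after TMM scaling, given as mean ± SD over 3 samples.

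Before the data were examined, 33 gene lists were fixed, covering toxicant, antioxidant, inflammatory and stress responses, immune and lung cell types, and tissues that a piece of lung can carry. Each list was tested in every contrast against control by camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01 between genes, adjusted over the 33 lists of a contrast. Its use on the dose slopes, the difference between days and the comparison of the controls was not fixed in advance. The same test with an estimated correlation, and fry, which asks whether the members of a list move on balance one way, were run beside it. The mean log2 CPM of a list's members was compared between 3 and 3 samples by an exact two-sided permutation test, whose smallest possible p is 0.1. The SE of a list's mean comes from a linear model of that mean over the libraries, with the same groups. It measures the spread between libraries. The camera p with the preset correlation compares a list's members with the other genes and does not measure that spread. Counts adjusted over the list alone used the members' edgeR p-values.

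The genes named in the text were chosen by a rule written before the data were examined. It took, for 20 mg/mL at each day, the 8 largest rises and the 8 largest falls among genes past the threshold with at least 1 CPM in the higher group and no overlap between exposed and control samples. It took 3 each way for the lower doses and 5 each way for the other contrasts, and up to 4 called members of each list. Unnamed gene models were left out. Where fewer than 10 genes passed, every one was named. Cyp1a1, Cyp1b1, Nqo1, Hmox1, Scgb1a1, Sftpc, Il1b, Il6, Tnf, Ccl2, Cxcl1 and Mmp12 were named whatever their p. Because so few genes passed, the other genes named were chosen after their values were seen, as the members of a list or the genes called by another tool with the smallest p.

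Alternatives fixed in advance were size factors by the RLE method, upper-quartile scaling, no filter beyond 1 read, DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, the replicate number within each day as a block, a test against a 1.5-fold change, dose weights by rank, and the removal of each sample in turn. Added after seeing the data were 2 surrogate variables from sva 3.50.0 as covariates, the number of genes detected at equal depth (counts thinned to 4520113 reads) as a covariate, removal of ribosomal RNA and globin genes, and removal of the 8 libraries with the fewest detected genes. Removing those 8 libraries leaves only replicate 3 of 5 mg/mL and of 10 mg/mL at day 6. The mean of the dose slopes of both days, 1 contrast over all 24 samples, was also added after seeing the data. Alternatives for normalized values were not needed, because the files hold counts.

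The fit was tested on simulated data with the group sizes and spread of this series, 5 data sets of up to 11296 tested genes. For 20 mg/mL against control at day 6, it recovered 1.20% of genes changed 1.5-fold, 23.6% of those changed 2-fold, 68.4% of those changed 4-fold and 83.6% of those changed 8-fold, and 2.86% of its calls were false. It called 0 genes and 0 lists on an unchanged data set. The simulated genes varied independently, so the list test was not checked for genes that vary together. With the real samples and exchanged labels, camera called up to 10 lists in a comparison with control. Gene order on the chromosome was taken from a RefSeq table on the assembly GRCr8, which is not the build rn6 of the counts, and was used for neighbouring genes only.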

Results

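The series followed the lung transcriptome of rats exposed repeatedly to WCSC, a condensate of the smoke of whole cigarettes. It asked how expression in the damaged lung depended on dose and on the length of exposure. There were 3 samples each of control lung and of lung exposed to 5, 10 and 20 mg/mL at 6 days, and the same 4 groups at 12 days. Total counts per sample ranged from 4.80e+06 to 1.11e+07, and 11421 genes were tested. Samples of a group correlated at 0.912 to 0.971 in log2 CPM (median 0.943), and samples of different groups of the same day had a median of 0.946. The 8 libraries with the fewest detected genes had 11364 to 11634 genes at equal depth, against 11786 to 12306 in the other 16, and 6 of these 8 were from day 6 (1 control, 2 at 5 mg/mL, 2 at 10 mg/mL and 1 at 20 mg/mL). Tissue content differed as well. Replicate 2 of 20 mg/mL at day 12 had a mean log2 CPM of 7.89 for heart muscle genes, against at most 3.68 in every other library. It also had the highest values of the club and goblet cell list (8.59) and the ciliated cell list (5.59) among the 24 libraries. Replicate 3 of 20 mg/mL at day 6 ranked 2 in these 3 lists, and control replicate 2 of day 12, which enters every comparison of that day, ranked 3 (3.45 for heart muscle, where the other libraries had a median of 0.66, 6.63 for club and goblet cells and 4.57 for ciliated cells).

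In lungs exposed to 20 mg/mL for 6 days, the gene with the smallest p was Cebpd, which encodes an inducible C/EBP transcription factor of the inflammatory response. Its level was 76.1 ± 14.1 CPM against 243 ± 41.8 CPM in control (mean ± SD, n = 3 each), a log2 fold change of -1.68 (SE 0.27), and all 3 exposed libraries lay below all 3 controls. Its adjusted p in edgeR was 0.0524. Nfkbia, the inhibitor that NF-kappaB itself induces, was at 802 ± 154 CPM against 1793 ± 180 CPM (log2 fold change -1.16, SE 0.28). The transcription factor gene Zbtb16 was at 64.4 ± 0.925 CPM against 5.30 ± 3.95 CPM (log2 fold change 3.60, SE 0.88), and the linker histone gene Hist1h1d at 163 ± 26.7 CPM against 65.3 ± 1.14 CPM (log2 fold change 1.32, SE 0.29). Epha4, an ephrin receptor gene, had a log2 fold change of -1.03 (SE 0.21). In edgeR 0 genes passed the adjusted threshold, while 464 genes had an unadjusted p under 0.05, where chance alone gives 571. DESeq2 called 3 genes (Cebpd, Epha4 and Hist1h1d), and limma voom with sample quality weights called 2 (Cebpd and Zbtb16). The log2 fold change of Cebpd lay between -1.82 and -1.53 under all 18 alternatives, but its call depended on them. It passed in edgeR with RLE scaling (adjusted p = 0.0474), without the expression filter (0.0266), with the number of detected genes as a covariate (0.0118), with 2 surrogate variables (0.0138) and without the 8 libraries with the fewest detected genes (0.0278). It did not pass with upper-quartile scaling (0.0649), in a fit of these 2 groups alone (0.212), without ribosomal RNA and globin genes (0.0549), against a 1.5-fold change (0.717) or without any 1 of the 6 libraries (0.0657 to 0.540).

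Macrophage genes rose as a group at day 6 and 20 mg/mL. In the list for lipid-laden macrophages, 18 of 21 members had a higher mean, the mean log2 fold change was 0.50, and the camera adjusted p was 1.65e-05. The adjusted p was 0.130 with an estimated correlation. Without exposed replicate 3 the mean log2 fold change of this list was 0.27, and the call was kept (adjusted p = 0.00772). At 10 mg/mL and day 6 the lipid-laden list went the other way, with a mean of -0.25 and an adjusted p of 0.504. The list was called lower there with 2 surrogate variables (mean -0.38, adjusted p = 0.00336) and with the number of detected genes as a covariate (-0.29, 0.0314). Leaving out exposed replicate 1 (-0.41, 0.00448) or control replicate 2 (-0.41, 0.0146) also gave this call. Removing the 8 libraries with the fewest detected genes leaves only replicate 3 of 10 mg/mL, and the mean of the lipid-laden list was then -0.57. Its members Gpnmb (439 ± 269 CPM against 210 ± 46.0 CPM), Trem2 (19.9 ± 15.1 CPM against 8.47 ± 3.52 CPM) and Mmp12, the macrophage elastase (12.8 ± 16.2 CPM against 1.46 ± 1.19 CPM) had log2 fold changes of 1.06, 1.24 and 3.12. All 16 measured members of the macrophage identity list had a higher mean (mean log2 fold change 0.52, camera adjusted p = 0.000148), and its adjusted p was 0.260 with an estimated correlation. Its members included the lysosomal marker Cd68 (log2 fold change 0.96) and the endotoxin co-receptor Cd14 (log2 fold change 1.30). In both lists 0 members passed adjusted over the list alone. The mean of each list lay above all 3 controls in all 3 exposed libraries (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows). For the lipid-laden list the margin was small, with exposed replicate 1 at 5.79 and control replicate 3 at 5.78 log2 CPM. Of the 33 lists 4 reached that p, and the smallest exact p adjusted over the lists was 0.733. The separation is therefore weak evidence of a rise. Blood content differed beside these lists: globin took 5.42%, 8.27% and 1.36% of the counts in exposed replicates 1, 2 and 3 and 7.34%, 5.44% and 3.50% in the controls. The red blood cell list had a mean of -0.34 and an adjusted p of 0.225 at 20 mg/mL and day 6. It was called lower there with 2 surrogate variables (mean -0.40, adjusted p = 0.0392), without the 8 libraries with the fewest detected genes (-0.64, 0.0198), without exposed replicates 1 (-0.56, 0.0388) or 2 (-0.93, 2.83e-05) and without control replicate 3 (-0.67, 0.00996).

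The cell cycle list also rose in lungs exposed to 20 mg/mL at day 6, with 24 of 28 members higher. Its mean log2 fold change was 0.40 (SE 0.29) and its camera adjusted p was 0.000179 (adjusted p = 0.424 with an estimated correlation). Its member Ccnb1, the mitotic cyclin, was at 16.7 ± 7.84 CPM against 5.88 ± 2.32 CPM. Complement genes (14 of 16 higher, adjusted p = 0.00459), MHC class II and dendritic cell genes (11 of 15 higher, adjusted p = 0.00792), surfactant and type II cell genes (11 of 13 higher, adjusted p = 0.0152) and T and NK cell genes (18 of 23 higher, adjusted p = 0.0371) were called higher by the same test. For each of these 4 lists the adjusted p was also 0.424 with an estimated correlation. RT1-Db1, an MHC class II beta chain gene, was at 910 ± 258 CPM against 430 ± 92.9 CPM (log2 fold change 1.08), and it and RT1-DMa passed adjusted over the list alone. In the cell cycle, complement, type II cell and T and NK cell lists 0 members did. None of these 4 lists and the cell cycle list was called without replicate 3 of the exposed group (means of 0.02, -0.05 and 0.10 for cell cycle, MHC class II and T and NK cell genes, adjusted p = 0.703 each, 0.15 and 0.365 for type II cells, and 0.18 and 0.222 for complement). Without exposed replicate 2 the means were larger, at 0.84 for cell cycle (adjusted p = 1.37e-12), 0.58 for T and NK cell and 0.59 for MHC class II genes, and without the 8 libraries with the fewest detected genes they were 0.93, 0.66 and 0.56. Exposed replicate 3 had the highest means of the ciliated, club and goblet, and heart muscle lists after replicate 2 of 20 mg/mL at day 12. Without control replicate 2, the mean was 0.36 for T and NK cells (adjusted p = 0.0986), 0.21 for type II cells (0.0878) and 0.23 for complement (0.0717), against 0.35, 0.25 and 0.30 with all libraries. The T and NK cell mean was 0.24 without control replicate 3 (0.285). The type II mean was as large as with all libraries where its call was lost without exposed replicate 2 (mean 0.25, adjusted p = 0.0662) and without the 8 libraries with the fewest detected genes (0.28, 0.0533).

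**Figure D1:**
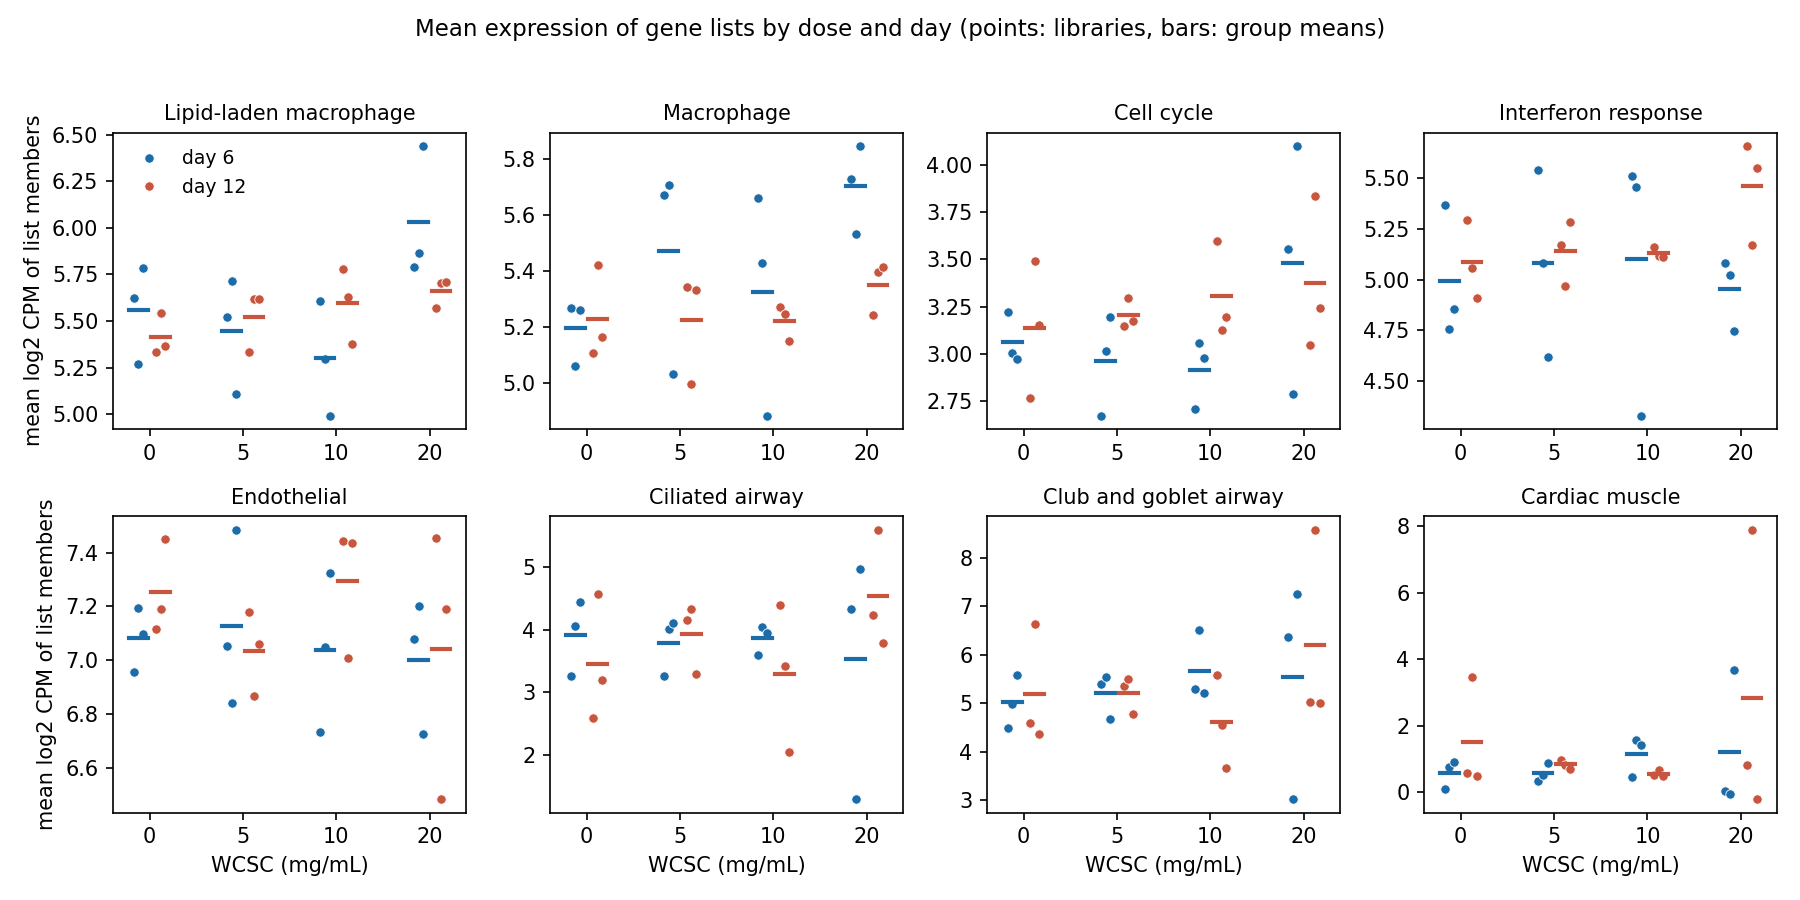
Mean log2 CPM of the members of 8 gene lists by WCSC dose (0, 5, 10 and 20 mg/mL) and day, with 1 point per library (n = 3 per group) and a bar at each group mean. At day 6 the 3 libraries at 20 mg/mL lie above the 3 controls in both macrophage panels, and in the cardiac muscle panel 1 library at 20 mg/mL and day 12 stands at 7.89, with every other library at 3.68 or lower.

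The genes and programmes that smoke toxicants are known to induce were measured at both days. Cyp1a1, the classical target of the aryl hydrocarbon receptor, had a log2 fold change of -0.23 at day 6 (95% interval -1.75 to 1.29) and of 0.59 at day 12 (95% interval -0.97 to 2.15). The sign of the Cyp1a1 change at day 6 turned positive without exposed replicate 3 and without control replicate 2. Nqo1, a quinone reductase, had log2 fold changes of -0.16 (95% interval -0.61 to 0.29) and -0.07 (95% interval -0.52 to 0.39), intervals that exclude a rise above 0.39. Hmox1, heme oxygenase, had 0.07 and 0.38 at 20 mg/mL, and 1.31 (SE 0.34) at 10 mg/mL and day 12, where its adjusted p was 1.00. The list of aryl hydrocarbon receptor targets had camera adjusted p of 0.187 at day 6, with all 7 measured members lower, and 0.961 at day 12, where 1 member (Lrat) passed adjusted over the list alone. The NRF2 antioxidant list had adjusted p of 0.414 and 0.198, with mean log2 fold changes of 0.12 and 0.15 over 24 members and 0 of them past the threshold adjusted over the list alone. At day 6 the NRF2 list was called higher without control replicate 1 (mean 0.28, adjusted p = 0.0248), and the aryl hydrocarbon receptor list lower without exposed replicate 1 (mean -0.55, adjusted p = 0.0465). Cyp1b1 (18 counts in 5 libraries) and Il6 (13 counts in 5 libraries) were too low to test.

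Among inflammatory genes, Il1b was at 58.7 ± 4.36 CPM against 35.0 ± 17.1 CPM at day 6 (log2 fold change 0.74, 95% interval 0.04 to 1.44) and at 41.2 ± 11.8 CPM against 58.8 ± 12.9 CPM at day 12 (log2 fold change -0.51, 95% interval -1.21 to 0.19). The monocyte chemokine gene Ccl2 had log2 fold changes of 2.11 (SE 0.81) and 1.25 (SE 0.79). Tnf had 0.31 at day 6 and 3.01 (SE 1.26) at day 12, from 1.58 ± 0.381 CPM against 0.195 ± 0.203 CPM. Cxcl1, a neutrophil chemokine, had 0.36 and -0.75, and Mmp12 had 3.12 (SE 1.06) and 1.42 (SE 1.06). Scgb1a1, the club cell secretoglobin, had -0.87 (SE 0.48) and 0.24, and Sftpc, the surfactant protein of type II cells, had 0.29 and -0.17. The signs of Tnf, Cxcl1 and Hmox1 at day 6 and of Nqo1, Sftpc and Cxcl1 at day 12 turned when 1 library was left out, and those of Scgb1a1 and Mmp12 at day 12 with 2 surrogate variables. The adjusted p of each of these genes was 1.00 at day 6 and 0.998 at day 12 in edgeR. The cytokine and NF-kappaB list (camera adjusted p = 0.382 and 0.919), the type 2 and eosinophil list (0.884 and 0.394), the neutrophil list (0.116 and 0.0900), the matrix and fibroblast list (0.589 and 0.0697), the ER stress list (0.0838 and 0.611) and the p53 list (0.210 and 0.676) did not pass at 20 mg/mL at either day. Some alternatives called them: with the number of detected genes as a covariate the neutrophil list was higher at day 6 (adjusted p = 0.0459) and lower at day 12 (0.0211). The neutrophil list was also called higher at day 6 without control replicate 1 (0.0198) and without the 8 libraries with the fewest detected genes (0.0115), and lower at day 12 with 2 surrogate variables (0.000623). The ER stress list was higher at day 6 with the covariate of detected genes (0.0478) and without control replicate 1 (0.0245). The matrix list was higher at day 12 without exposed replicates 1 (0.0300) and 3 (0.000941), without control replicate 3 (0.0153) and without the 8 libraries (0.0206). Of the cytokine list, Nfkbia passed adjusted over the list alone at day 6.

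**Figure D2:**
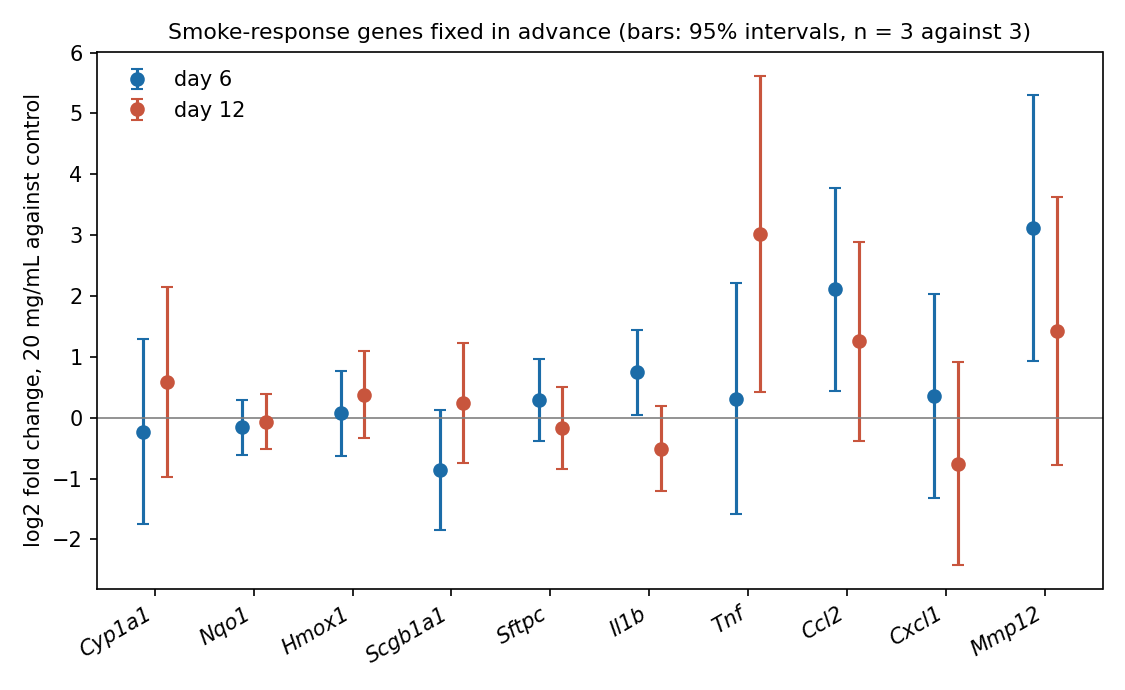
Log2 fold change of 20 mg/mL against control for 10 genes fixed in advance, at day 6 and at day 12, with 95% intervals from the edgeR fit (n = 3 against 3). The Nqo1 intervals reach from -0.61 to 0.29 and from -0.52 to 0.39, and the intervals of Mmp12, Ccl2 and Il1b at day 6 and of Tnf at day 12 lie above 0 without an adjustment for the number of genes.

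At the lower doses for 6 days, Cebpd was at 228 ± 87.3 CPM with 5 mg/mL and at 110 ± 21.6 CPM with 10 mg/mL (log2 fold changes -0.09 and -1.15). Zbtb16 was at 17.6 ± 27.5 CPM and 33.2 ± 18.0 CPM. Cmc1, which encodes a mitochondrial assembly factor of cytochrome c oxidase, was at 27.5 ± 13.0 CPM with 5 mg/mL against 8.78 ± 2.55 CPM in control (log2 fold change 1.65, SE 0.35), and the T cell adaptor gene Trat1 was at 2.62 ± 2.02 CPM where all 3 controls had 0. Trat1 also had the smallest p between the controls of day 12 and day 6 (unadjusted p = 0.000595 in edgeR). An effect of exposure on Trat1 could therefore not be told from its absence in these 3 controls. Mast cell genes rose as a list at 10 mg/mL (11 of 12 members higher, mean log2 fold change 1.15, camera adjusted p = 0.00678; adjusted p = 0.969 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. That call was lost without exposed replicate 1 (mean 0.42, adjusted p = 0.526) and without control replicate 3 (mean 0.76, adjusted p = 0.252). Removing the 8 libraries with the fewest detected genes leaves only replicate 3 of 10 mg/mL, and the list's mean was then 0.39. With 2 surrogate variables the mean of the mast cell list was 0.04 (adjusted p = 0.699). At 5 mg/mL 0 of the 33 lists were called. Without exposed replicate 3 the macrophage identity (mean 0.51, camera adjusted p = 0.0201), T and NK cell (0.58, 0.0201) and mast cell lists (1.30, 0.00820) were called higher there. That fit keeps 2 exposed libraries, both among the 8 with the fewest detected genes. In edgeR 0 genes passed at either dose. An unadjusted p under 0.05 was found for 538 genes at 5 mg/mL and 308 genes at 10 mg/mL. These counts were 1943 without replicate 3 of 5 mg/mL, where 2 genes passed, and 1540 without replicate 3 of 10 mg/mL. The exposed libraries that remain there are all among the 8 with the fewest detected genes. Without control replicate 1, also among those 8, the counts were 1112 and 940. With the number of detected genes as a covariate they were 639 and 330, and by limma voom with sample quality weights 2250 and 2963, against 571 by chance. DESeq2 called 2 genes (Trat1 and Cmc1) and 0 genes. Limma voom with sample quality weights called 0 genes and 5 genes (Ap2s1, Cebpd, Adam19, Ier5 and Pde4b).

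In lungs exposed to 20 mg/mL for 12 days, Fkbp5, a co-chaperone gene that glucocorticoids induce, was at 94.3 ± 47.0 CPM against 26.9 ± 4.64 CPM in control (log2 fold change 1.81, SE 0.39; adjusted p = 0.594 in edgeR). Zbtb16 was at 66.4 ± 31.0 CPM against 4.74 ± 1.32 CPM (log2 fold change 3.81, SE 0.91). Klf10, a TGF-beta-inducible transcription factor gene, had a log2 fold change of 1.23 (SE 0.27), and the fatty acid desaturase genes Scd2 and Scd1 had -0.90 (SE 0.21) and -1.46 (SE 0.38). Krt15, a keratin of basal epithelial cells, was at 40.0 ± 58.8 CPM against 1.78 ± 1.18 CPM. Its list of squamous and upper airway genes had this 1 tested member, and Krt15 had its highest value in replicate 2, the library with the high heart muscle and airway means. In edgeR 0 genes passed, 421 genes had an unadjusted p under 0.05, DESeq2 called 4 (Krt15, Fkbp5, Klf10 and Scd2), and limma voom with sample quality weights called 2 (Zbtb16 and Fkbp5).

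The interferon response list rose at day 12 and 20 mg/mL, with 18 of 21 members higher, a mean log2 fold change of 0.39 and a camera adjusted p of 0.00165, and adjusted p = 0.626 with an estimated correlation. Its antiviral members Mx1 (65.2 ± 8.58 CPM against 31.3 ± 7.70 CPM) and Mx2 (45.0 ± 15.1 CPM against 26.9 ± 3.58 CPM) had log2 fold changes of 1.06 and 0.75, and 0 members passed adjusted over the list alone. The call was kept without each of the 6 libraries in turn (highest adjusted p 0.0404). The groups overlapped, with list means of 5.66, 5.17 and 5.55 log2 CPM in exposed replicates 1, 2 and 3 and 5.29, 5.06 and 4.91 in the controls. Endothelial genes (18 of 19 lower, mean log2 fold change -0.22, adjusted p = 0.00165), type I cell genes (12 of 14 lower, mean -0.35, adjusted p = 0.00236) and type II cell genes (9 of 13 lower, mean -0.25, adjusted p = 0.0217) fell as lists. Ciliated cell genes (12 of 14 higher, mean 1.09, adjusted p = 0.00343) rose. For all 4 the adjusted p was 0.626 with an estimated correlation, and 0 members passed adjusted over the list alone. In the same group, 9 of the 10 measured heart muscle genes passed adjusted over the list alone. So did Cfd, Retn and Pck1 of the adipose list and Bpifa1 and Clca1 of the club and goblet list. The heart muscle means were 0.82, 7.89 and -0.20 log2 CPM in exposed replicates 1, 2 and 3. In the controls they were 0.57, 3.45 and 0.48, so the rise rested on exposed replicate 2. Actc1, cardiac actin, was at 368 ± 574 CPM against 53.1 ± 17.2 CPM, a spread set by replicate 2. Without that library the mean was 0.06 for endothelial (adjusted p = 0.983), 0.02 for type I (0.797), 0.05 for type II (0.606) and 0.60 for ciliated genes (0.319). The type II call was also lost without control replicate 1 (adjusted p = 0.0679) or 2 (0.108), with its mean about as large (-0.23 in each), and the ciliated call without control replicate 3 (mean 0.90, adjusted p = 0.0830). With 2 surrogate variables 0 of these 4 lists were called (means of 0.09 for endothelial, 0.00444 for type I, -0.14 for type II and -0.04 for ciliated genes; adjusted p = 0.763, 0.959, 0.128 and 0.543). With them the club and goblet list was called lower (mean -0.63, adjusted p = 0.00591), and Krt15 as the squamous list (2.60, 0.00486) and the glucocorticoid list (0.57, 0.00461) were called higher.

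Genes of B and plasma cells fell as a list at both lower doses at day 12, which share the same 3 controls. The list means were 3.91, 3.68 and 3.26 log2 CPM in these controls, against 3.11, 3.29 and 3.29 in the day 6 controls. They were 2.94, 2.82 and 2.68 at 5 mg/mL and 3.28, 2.90 and 2.65 at 10 mg/mL. The falls are therefore not independent, and an effect of exposure could not be told from high values in these controls. At 5 mg/mL 11 of 12 members were lower (mean log2 fold change -0.80, camera adjusted p = 1.17e-06; adjusted p = 0.0757 with an estimated correlation). The call was kept without each of the 6 libraries in turn (highest adjusted p 0.00216). At 10 mg/mL all 12 were lower (mean -0.68, adjusted p = 0.000671; adjusted p = 0.540 with an estimated correlation). The adjusted p was 0.0515 without exposed replicate 3 and 0.0522 without control replicate 1 (mean -0.54 in each), and 0.0817 without the 8 libraries with the fewest detected genes (mean -0.49). At 20 mg/mL the same B and plasma cell list had a mean of -0.35 and an adjusted p of 0.224. There it was called lower without exposed replicate 2, the library with the high heart muscle and airway means (mean -0.76, adjusted p = 0.0105), without control replicate 3 (mean -0.68, adjusted p = 0.0211) and with 2 surrogate variables (mean -0.54, adjusted p = 0.0252). Red blood cell genes were also called lower at 5 mg/mL (9 of 9 lower, mean -0.64, adjusted p = 0.000458) and at 10 mg/mL (8 of 9 lower, mean -0.67, adjusted p = 0.0112), with adjusted p of 0.875 and 0.917 with an estimated correlation. Those calls were lost without exposed replicate 3 (means -0.35 and -0.68, adjusted p = 0.179 and 0.0848) and without control replicate 1 (-0.52 and -0.55, adjusted p = 0.0504 and 0.130). The call at 10 mg/mL was also lost without ribosomal RNA and globin genes, where the mean was larger (-0.82, adjusted p = 0.0736), and without the 8 libraries with the fewest detected genes (-0.55, 0.0956). At 20 mg/mL and day 12 the red blood cell list had a mean of -0.74 and an adjusted p of 0.0815, and it was called lower without exposed replicate 1 (-1.06, 0.0123) and without control replicate 3 (-0.82, 0.0369).

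At 5 mg/mL and day 12, neutrophil genes (7 of 11 lower, mean log2 fold change -0.66, adjusted p = 0.000680; adjusted p = 0.198 with an estimated correlation) and endothelial genes (16 of 19 lower, mean -0.24, adjusted p = 0.00612; adjusted p = 0.875 with an estimated correlation) fell as lists. Heat shock genes rose (9 of 12 higher, mean 0.30, adjusted p = 0.00660; adjusted p = 0.380 with an estimated correlation). The neutrophil call was lost without exposed replicate 3 (mean -0.41, adjusted p = 0.111). Both other calls were lost without exposed replicate 2 (means -0.13 and 0.17, adjusted p = 0.0588 and 0.353 for endothelial and heat shock genes) and without control replicate 3 (-0.10 and 0.25, adjusted p = 0.0738 and 0.201). The endothelial call was also lost without control replicate 1 (adjusted p = 0.0613) and without the 8 libraries with the fewest detected genes (0.0595), where its mean was larger (-0.32 and -0.33). At 10 mg/mL the immediate-early list, which responds to handling and tissue collection, rose (14 of 15 higher, mean 0.63, adjusted p = 0.000323; adjusted p = 0.917 with an estimated correlation). Its member Junb, at 129 ± 70.5 CPM against 46.0 ± 7.92 CPM, passed adjusted over the list alone. That list had a mean of 0.08 and an adjusted p of 0.635 without exposed replicate 3. In the other lists called at these doses 0 members passed adjusted over the list alone. In edgeR 0 genes passed at either dose, and 143 genes at 5 mg/mL and 239 genes at 10 mg/mL had an unadjusted p under 0.05. DESeq2 called Gp2 at 5 mg/mL (0 CPM against 0.397 ± 0.539 CPM) and Ckmt2 at 10 mg/mL (0 CPM against 1.99 ± 3.44 CPM), and limma voom with sample quality weights called 0 genes at either dose.

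Expression was then tested for a slope over the 4 doses. At day 6 Cebpd fell with dose, by 0.09 log2 units per mg/mL (SE 0.01; adjusted p = 0.0126), the only gene past the threshold in edgeR, with 555 genes at an unadjusted p under 0.05. The slope kept its sign without each of the 12 libraries of that day, but its adjusted p was 0.110, 0.230 and 0.107 without replicates 1, 2 and 3 of 20 mg/mL and 0.0777 without control replicate 2. It was 0.212 in a fit of the day 6 groups alone and 0.152 against a change of 1.5-fold over the dose range. DESeq2 called 9 genes at day 6, among them Hist1h1d, RT1-Db1, Nfkbia, Spidr and Epha4 besides Cebpd, and limma voom with sample quality weights called 2 (Cebpd and Zbtb16). At day 12 edgeR called 0 genes, and 498 had an unadjusted p under 0.05. The smallest adjusted p was 0.181, shared by Klf10, Fkbp5, Krt15 and Zbtb16 (slopes of 0.06, 0.09, 0.22 and 0.21 log2 units per mg/mL). DESeq2 called 11 genes at day 12, among them these 4, and limma voom with sample quality weights called 3 (Zbtb16, Fkbp5 and Klf10). The same camera test called 6 of the 33 lists higher at day 6 and, at day 12, 3 higher and 3 lower, with smallest adjusted p over all 33 lists of 0.119 and 0.739 with an estimated correlation.

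The mean of the day 6 and day 12 slopes, a contrast chosen after seeing the data, passed the threshold for 3 genes, and 404 genes had an unadjusted p under 0.05. Cebpd fell by 0.06 log2 units per mg/mL (SE 0.01; adjusted p = 0.0105), from 243 ± 41.8 CPM in control to 76.1 ± 14.1 CPM with 20 mg/mL at day 6 and from 202 ± 65.4 CPM to 128 ± 18.9 CPM at day 12. Zbtb16 rose by 0.19 log2 units per mg/mL (SE 0.03; adjusted p = 0.0135), and its 10 mg/mL groups, at 33.2 ± 18.0 CPM and 25.0 ± 3.20 CPM, lay between control and 20 mg/mL at both days. Spidr, a DNA repair gene, fell by 0.07 log2 units per mg/mL (SE 0.01; adjusted p = 0.0258), from 67.6 ± 20.3 CPM to 24.7 ± 5.24 CPM at day 6 and from 72.9 ± 29.4 CPM to 29.2 ± 5.79 CPM at day 12. Cebpd and Spidr are neighbours on the chromosome with 0 genes between them in the GRCr8 annotation. The strand setting of the counting is not stated, so the Spidr counts could not be separated from reads of Cebpd. Fkbp5 and Krt15 followed with adjusted p of 0.0675 each. Fkbp5 was called besides the 3 with the number of detected genes as a covariate. DESeq2 called 10 genes and limma voom with sample quality weights 6, both including the 3 named.

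Cebpd was called without each of the 24 libraries in turn, with adjusted p up to 0.0391. Zbtb16 was lost without control replicates 2 and 3 of day 12 (adjusted p = 0.0643 and 0.0887). Spidr was lost without replicates 1 and 3 of 20 mg/mL at day 6 (adjusted p = 0.164 and 0.110), control replicate 2 of day 6 (0.0935), replicates 1, 2 and 3 of 20 mg/mL at day 12 (0.0681, 0.0566 and 0.05001) and control replicate 3 of day 12 (0.0887), and also without the 8 libraries with the fewest detected genes (0.0764). Against a change of 1.5-fold over the dose range, 0 of the 3 genes passed.

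**Figure D3:**
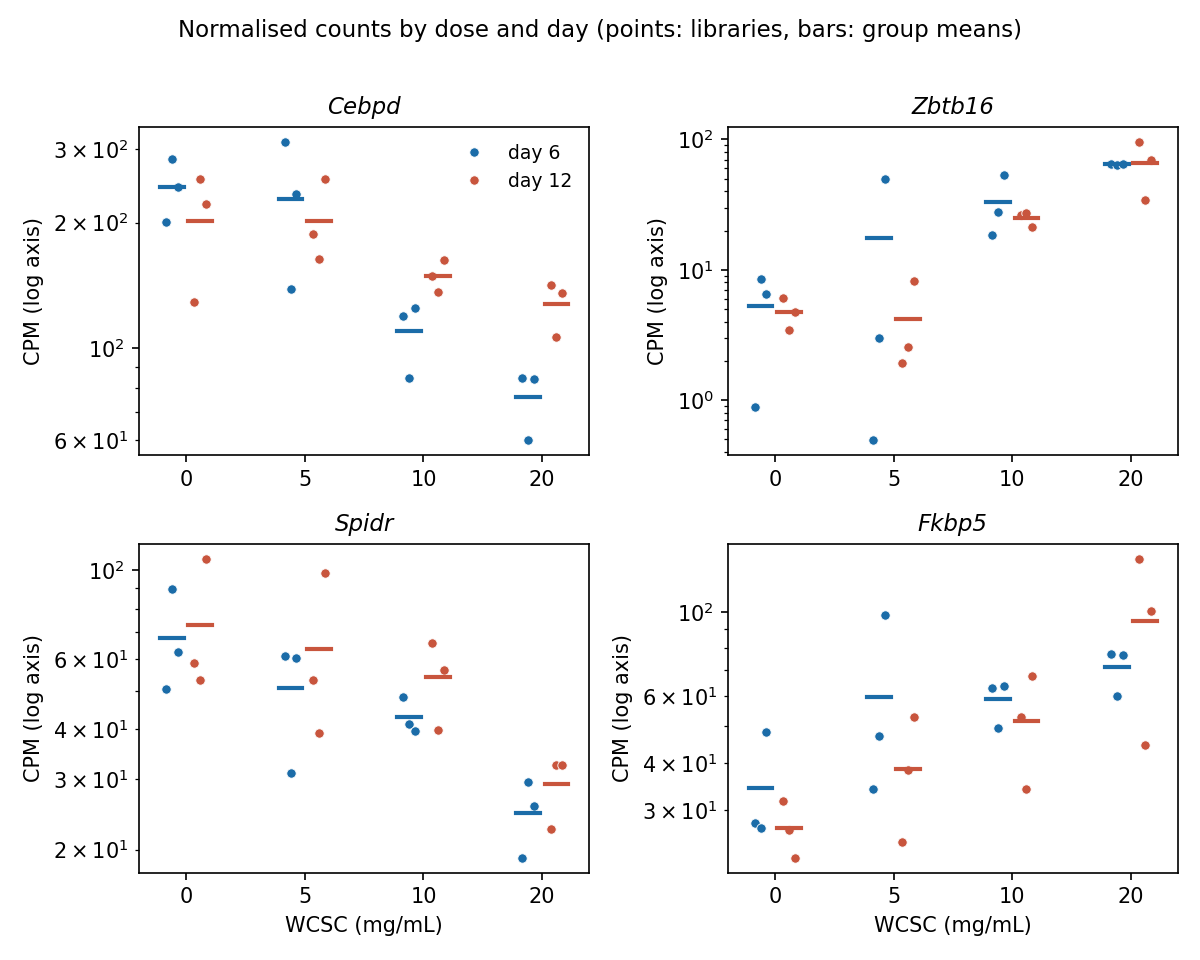
CPM (log axis) of Cebpd, Zbtb16, Spidr and Fkbp5 by WCSC dose (0, 5, 10 and 20 mg/mL) and day, with 1 point per library (n = 3 per group) and a bar at each group mean. From control to 20 mg/mL, the Cebpd means go from 243 to 76.1 CPM at day 6 and from 202 to 128 CPM at day 12, and the Zbtb16 means from 5.30 to 64.4 CPM and from 4.74 to 66.4 CPM.

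Whether the 20 mg/mL effect differed between the days was tested directly. In edgeR and in DESeq2 0 genes passed, as in limma voom with sample quality weights, and 435 genes had an unadjusted p under 0.05 in edgeR. The Cebpd effect differed by 1.02 (SE 0.39; adjusted p = 1.00), the Il1b effect by -1.26 (SE 0.48) and the Zbtb16 effect by 0.20 (SE 1.26). The camera test called 6 lists for this difference, with a smallest adjusted p of 0.564 with an estimated correlation. Across the 11421 genes, the log2 fold changes of 20 mg/mL at the 2 days, which have separate controls, had a Pearson correlation of 0.135 and a Spearman correlation of 0.02, and 50.6% of genes had the same sign. Genes are not independent replicates. Without replicate 3 of 20 mg/mL at day 6 the Pearson correlation was -0.0607, and without replicate 2 of 20 mg/mL at day 12 it was -0.0627. An unadjusted p under 0.05 at both days with the same sign was found for 17 genes, where 8.60 arise by chance, and with opposite signs for 9. Cebpd, Spidr, Zbtb16, Fkbp5, Nfkbia and the transcription factor gene Tox3 (log2 fold changes -0.77 and -0.68) were among the 17. So were Scgb3a1, Clca1 and Bpifa1 of the club and goblet list. The mean of that list was highest in replicate 2 of 20 mg/mL at day 12 and next in replicate 3 of 20 mg/mL at day 6. For such genes a shared effect of exposure could not be told from airway content.

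The doses of a day share their 3 controls, which correlates their changes without any effect of exposure. At day 6 the log2 fold changes correlated at 0.547 between 5 and 10 mg/mL, 0.379 between 5 and 20 mg/mL and 0.461 between 10 and 20 mg/mL, against 0.503, 0.503 and 0.497 simulated for unchanged groups with the same controls. At day 12 the correlations were 0.556, 0.282 and 0.293, against 0.511, 0.508 and 0.505. The covariance exceeded the simulated one only for 5 and 10 mg/mL at day 6 (0.179 against 0.155, SD of the simulations 0.00869), and the other 5 differences lay between -0.0736 and -0.00696. With 3 controls no split leaves 2 libraries on each side, so the part of each correlation that comes from the shared controls could not be removed. Between 20 mg/mL and either lower dose, the correlations of both days were smaller than those simulated for shared controls alone. Those correlations therefore give no sign of an effect common to the doses. No gene was called at any dose by edgeR, so there was no overlap of called genes to count.

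The controls of day 12 and day 6 were compared as the background of the time course. In edgeR 0 genes passed, with 281 at an unadjusted p under 0.05, and DESeq2 and limma voom with sample quality weights called 0 as well. The smallest unadjusted p in edgeR was that of Trat1 (0.000595), which was at 0 CPM in all day 6 controls. Red blood cell genes were lower as a list in the day 12 controls (8 of 9 lower, mean log2 fold change -0.70, camera adjusted p = 0.00193; adjusted p = 0.895 with an estimated correlation). Cebpd was at 202 ± 65.4 CPM in the day 12 controls and 243 ± 41.8 CPM in the day 6 controls, and Zbtb16 at 4.74 ± 1.32 CPM and 5.30 ± 3.95 CPM.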

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

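The gene lists, the estimated correlation, the removal of each library and the edgeR test of the difference between days were fixed in advance, while the camera and permutation tests of that difference, the count of opposite separation and the tests of explanations were chosen after seeing the data. Each of 6 gene lists had a 20 mg/mL effect that differed between day 12 and day 6 in the camera test of that difference. Among the genes singled out by the rule or after their values were seen, 2 had exposed libraries all above the controls at day 6 and all below them at day 12. For neutrophil genes the difference in log2 fold change was -0.89, from 0.41 at day 6 to -0.48 at day 12 (camera adjusted p = 0.0204; 0.564 with an estimated correlation; exact permutation p = 0.01, adjusted over the lists 0.165). For lipid-laden macrophage genes it was -0.24 (exact permutation p = 0.560), for interferon response genes 0.45 (exact permutation p = 0.185), and for MHC class II and dendritic cell genes -0.30 (exact permutation p = 0.520). Type II cell genes differed by -0.50 (exact permutation p = 0.125) and ciliated cell genes by 1.78 (exact permutation p = 0.315). These differences moved with individual libraries: without replicate 2 of 20 mg/mL the ciliated effect at day 6 was 0.83 instead of -0.69, and without replicate 3 it was -1.69. Without replicate 2 of 20 mg/mL at day 12, the type II effect there was 0.05 instead of -0.25 and the ciliated effect 0.60 instead of 1.09. The smallest adjusted p of these lists with an estimated correlation was 0.564. Tmem242 differed by -1.10 (SE 0.31) and Cfp, the complement factor properdin, by -0.83 (SE 0.29), each with an adjusted p of 1.00 in edgeR. Such opposite separation was found for 47 of 11421 genes (0.412%), where chance gives 0.5%.

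Macrophage genes were higher at 20 mg/mL and day 6, a call that was lost with an estimated correlation (adjusted p = 0.130 for the lipid-laden list and 0.260 for the identity list). The call did not rest on 1 library, with a highest camera adjusted p of 0.0106 when each of the 6 was left out, but the size did in part: without replicate 3 of 20 mg/mL the lipid-laden mean was 0.27 instead of 0.50. The other 5 lists called there could come from 1 library, since 0 of them were called without replicate 3 of 20 mg/mL, where their means were -0.05 to 0.18 (SE 0.19 to 0.28) instead of 0.25 to 0.40 (SE 0.17 to 0.29). Low gene detection was argued against, with 7 of the 7 lists still called when the number of detected genes was a covariate. An effect of 20 mg/mL at either day could not be told from one limited to day 6. The mean log2 fold change of the macrophage lists at day 12 was 0.17. The lipid-laden mean was 0.25 there, and all exposed libraries (5.57 to 5.71 log2 CPM) lay above all controls (5.33 to 5.54). The identity list overlapped its controls at day 12 (5.24 to 5.41 against 5.10 to 5.42). At 10 mg/mL and day 6 the lipid-laden list had a mean of -0.25 and was called lower under some alternatives.

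Cebpd, Zbtb16 and Spidr passed in the mean of the dose slopes of both days, a contrast chosen after seeing the data. In edgeR the slope of day 6 alone called only Cebpd, and that of day 12 alone called 0 genes. Low gene detection was argued against, as 3 of the 3 genes were called with the number of detected genes as a covariate, although without the 8 libraries with the fewest detected genes Spidr missed the threshold (adjusted p = 0.0764) with a slope of -0.08 instead of -0.07 log2 units per mg/mL. The time of day of sampling could shift such genes, but 0 of 13 clock genes passed adjusted over the list alone (Per2 had the smallest adjusted p in edgeR, 0.0913), which cannot tell. A glucocorticoid response, for instance from handling, could raise Zbtb16 and Fkbp5, and that list, both genes included, was called higher at day 12 at 20 mg/mL with 2 surrogate variables (mean 0.57, adjusted p = 0.00461) and at 10 mg/mL without exposed replicate 2 (0.55, 0.0221). Of its 8 other members 5 had a rising slope, while Dusp1 fell by 0.87 log2 units over 20 mg/mL (adjusted over the list alone 0.0173), which cannot tell either.

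Endothelial and alveolar genes were lower and ciliated genes higher at 20 mg/mL and day 12, calls that were lost with an estimated correlation (adjusted p = 0.626 for each, as for the interferon list). More airway and heart tissue in 1 library could account for these 4 lists, since 0 of them were called without replicate 2 of 20 mg/mL, where the endothelial, type I, type II and ciliated means were 0.06, 0.02, 0.05 and 0.60 (SE 0.24, 0.18, 0.10 and 1.00) instead of -0.22, -0.35, -0.25 and 1.09 (SE 0.25, 0.24, 0.17 and 0.91). With 2 surrogate variables 0 of the 4 were called either. The camera call of the interferon list of the same group was not carried by that library, as its highest adjusted p was 0.0404 when each of the 6 libraries was left out. That p does not measure the spread between libraries. The groups overlapped in this list, with exposed replicate 2 at 5.17 and control replicate 1 at 5.29 log2 CPM. The mean log2 fold change of the interferon list at 20 mg/mL and day 6 was -0.0578, which cannot tell whether exposure acts on it at either day. At 10 mg/mL and day 6 the list was called higher without exposed replicate 3 (0.45). Removing the 8 libraries with the fewest detected genes leaves only that replicate of 10 mg/mL, and the mean was then -0.62.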

How the results depend on the processing

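The comparison of the controls gave 0 genes under all 18 alternatives, and RLE or upper-quartile scaling changed no count of genes except at 20 mg/mL and day 6. For 13 named genes (the 10 of the fixed list that were tested, Cebpd, Spidr and Zbtb16), 510 of 553 values under alternatives kept their sign and their side of the threshold, 19 were weaker, 8 stronger and 16 reversed in sign. The 16 were of genes called in neither fit. With 1 library left out, log2 fold changes ranged at day 6 from -0.72 to 0.40 for Cyp1a1, -0.25 to 0.43 for Hmox1, -0.0977 to 0.92 for Tnf and -0.24 to 0.76 for Cxcl1, and at day 12 from -0.16 to 0.0580 for Nqo1, -0.49 to 0.20 for Sftpc and -1.16 to 0.36 for Cxcl1. The other reversals were Cxcl1 at day 6 (-0.0928) and Nqo1 at day 12 (0.00258) by voom, Nqo1 at day 12 without the 8 libraries (0.17), and Scgb1a1 (-0.12) and Mmp12 (-0.38) at day 12 with surrogate variables. The cause of the changes below was not tested, except that a test against a 1.5-fold change asks for more. By edgeR 23.6% of simulated 2-fold changes and 83.6% of 8-fold changes were found at this size and spread; the effect of depth was not tested.

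Genes called were: at 5 mg/mL and day 6, 2 by DESeq2; at 10 mg/mL and day 6, 5 by voom with quality weights and 1 with surrogate variables. At 20 mg/mL and day 6 there was 1 with RLE, without a filter and with the detection covariate, 3 by DESeq2, 2 by voom, 2 with surrogate variables and 3 without the 8 libraries. At day 12, DESeq2 gave 1, 1 and 4 at 5, 10 and 20 mg/mL, the groups alone 2 at 10 and 1 at 20 mg/mL, the removal of the 8 libraries 1 at 10 mg/mL, voom 2 and surrogate variables 3 at 20 mg/mL. The slope at day 6 gave 9 by DESeq2, 2 by voom, 0 with the groups alone, 0 against 1.5-fold, 2 with surrogate variables and 4 without the 8 libraries. The slope at day 12 gave 11 by DESeq2, 3 by voom, 1 with the groups alone, 2 with surrogate variables and 1 without the 8 libraries. The mean slope gave 6 without a filter, 10 by DESeq2, 6 by voom, 0 against 1.5-fold, 5 with surrogate variables, 6 without the 8 libraries and 4 with the detection covariate, and the difference between days 1 with surrogate variables. With 1 library left out, genes ranged from 0 to 2 at 5 mg/mL and day 6, 0 to 2 for the slope at day 6, 1 to 7 for the mean slope, and stayed at 0 elsewhere.

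With an estimated correlation or fry, 0 lists were called at every dose and day. Surrogate variables gave 1 list at 5 mg/mL and day 6. The removal of the 8 libraries leaves 1 exposed library at 5 and at 10 mg/mL and day 6, so its calls there are not counted. At 20 mg/mL and day 12 surrogate variables kept 1 of the 5 lists (interferon) and called 5 others. The detection covariate gave 2 at 10 mg/mL and day 6, and 8 and 9 at 10 and 20 mg/mL and day 12. The removal of the 8 libraries gave 1 and 9 at 10 and 20 mg/mL and day 12. With 1 library left out, lists ranged from 0 to 3, 0 to 2 and 3 to 11 at 5, 10 and 20 mg/mL and day 6, and from 3 to 6, 0 to 4 and 4 to 10 at day 12. The correlation between days was 0.252 over genes with p under 0.05 at either day, -0.0416 with surrogate variables, and -0.0627 to 0.207 with 1 library left out.

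Replicate numbers do not pair the samples by any label. With the number as a block, 1 gene (Cebpd, adjusted p = 0.0288 against 0.0524 without the block) was called at 20 mg/mL and day 6 and 11 lists at 20 mg/mL and day 12 (matrix and club and goblet genes higher and red blood cell genes lower, adjusted p = 0.0328 each, and heart muscle, mast cell and squamous genes higher besides the 5). The block also gave 4 genes for the mean slope (Fkbp5 added), the neutrophil list at 20 mg/mL and day 6 (adjusted p = 0.0340), and heart muscle genes lower at 5 and 10 mg/mL and day 12 (adjusted p = 0.000846 and 0.00115). Deviations from the group means of libraries with number 1, 2 and 3 had mean correlations of 0.207, -0.0750 and 0.332 at day 6 (every pair of number 3 at 0.212 to 0.591) and of -0.0369, 0.0819 and 0.0511 at day 12, against -0.0474 between numbers, and 13 of 24 libraries correlated best with their own number. Not every pair lay above 0.1, so the fit was kept without the block, but libraries of day 6 with number 3 shared variation. That fit, the other splits of the samples and the correlations simulated for unchanged groups take no account of it.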

Other observations

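The tests of this part were chosen after seeing the data, except the fit of only the groups compared, which was fixed in advance. At 10 mg/mL and day 12, the MHC class I gene RT1-A2 was at 1011 ± 105 CPM against 251 ± 72.7 CPM in control (log2 fold change 2.01, SE 0.52). It was called in a fit of these 2 groups alone and without the 8 libraries with the fewest detected genes, but not in the fit of all 24 samples. The gene was chosen after its values were seen.

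In the mean of the dose slopes of both days, the glucocorticoid-induced genes Zbtb16 and Fkbp5 had changes of 3.84 and 1.35 log2 units over 20 mg/mL (adjusted over the list alone 2.36e-05 and 0.000139). Dusp1, which glucocorticoids also induce, had -0.87 (adjusted over the list alone 0.0173), and Tsc22d3, another such gene, had -0.31.

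Group labels were exchanged between the same samples to see how many calls a division without regard to exposure gives, and the counts below include the real division as 1 of the splits. For genes, 10 of 10 splits gave at least as many calls as the real one in each of the 6 comparisons with control and in the comparison of the controls, where the real count was 0. A real count of 0 fixes that share in advance, so the share says nothing about exposure. The same holds below for the slope at day 12 and the difference between days, where the real count was also 0. The highest count of another split was 1470 at 5 mg/mL and 1180 at 10 mg/mL for day 6, and 0 in the other 5. For the slope at day 6, 14 of 100 splits gave at least 1 gene (13 besides the real one, highest 1487), for the slope at day 12 100 of 100 (highest 0), for the difference between days 100 of 100 (highest 6), and for the mean slope of both days 2 of 100 gave at least 3 (the real one and 1 other, with 1250). A split that calls so many genes points to sample structure.

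For lists at day 6, the splits with at least as many calls were 10, 9 and 4 of 10 at 5, 10 and 20 mg/mL (real counts 0, 1 and 7, highest others 5, 6 and 9). At day 12 they were 1 (the real one), 5 and 8 of 10 (real counts 5, 3 and 5, highest others 4, 5 and 10), and for the controls 7 of 10 (real count 1, highest other 4). With 10 splits a share under 0.05 cannot be reached. For the slopes they were 28 of 100 at day 6 and 45 of 100 at day 12 (real counts 6 and 6, highest others 12 and 14), 55 of 100 for the difference between days (real count 6, highest other 12) and 5 of 100 for the mean slope (real count 12, highest other 15).

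All 3 exposed libraries lay beyond all 3 controls, either way, for 8.75% of genes with 20 mg/mL at day 6 and for 7.67% at day 12, where chance gives 10%.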
